A study of Mus musculus with 4 samples.

How the data were processed

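The data were droplet single-cell RNA-seq libraries (10x Genomics Chromium 3′ v3) of hepatocyte preparations from 4 female mice, 1 library per CreERT2 line. Per the labels, 8000 hepatocytes were loaded to target 5000 cells per sample, and the libraries were sequenced on a NextSeq500. Per the series' design text, the authors made the matrices with Cell Ranger 3.0.2 (mkfastq and count), pooled the runs of the 4 mice with its aggr command and kept default parameters except force-cells, stated as 4000. The build was mm10 per the submitters' processing notes, and the annotation version was not given in the sources used here. The deposited values used here are raw UMI counts per gene and cell barcode in 1 filtered matrix per mouse, not the pooled one. These hold 4000, 4000, 5000 and 5000 barcodes in the order Cyp1a2, Gls2, Gls2/Oat and Hamp2 line, so the stated force-cells value holds for 2 of them; a filtered matrix of a forced size can include barcodes of low quality in proportions that differ between libraries. The feature list held 28694 features, of which 28692 were genes and the others the transgenes tdtomato and wpre; 28416 gene IDs were found in GENCODE M21, which gave the mm10 coordinates, and 67 features repeat a symbol.

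Cells were kept with at least 1000 UMIs, at least 500 genes and at most 40% of UMIs from mitochondrially encoded genes. The lowest barcode totals were 5216, 4240, 2330 and 2365 UMIs, so the UMI minimum removed nothing. The gene minimum removed 2, 3, 143 and 67 barcodes (215) and the mitochondrial limit 1572, 1486, 758 and 1195 (5011). Doublets were scored with Scrublet in scanpy 1.11.5 per library. Its automatic threshold marked 29 cells (0.163%), which is too few to have worked, so the 4% of each library with the highest scores were left out (97, 100, 164 and 150 cells, 511 in all). Counts were scaled to 10000 per cell and log-transformed, and the 2000 most variable genes, 30 principal components and 15 neighbours entered Leiden clustering at resolution 1 (leidenalg 0.10.2, scikit-learn 1.9.0), which gave the clusters numbered 0 to 30. Transgenes entered neither clustering nor scores. A cluster was named X-like from marker lists fixed beforehand, when at least 3 markers of 1 type were at least 4-fold above the other clusters (pseudocount 20 CPM) and at 50 CPM or more, hepatocyte markers lay below 0.5 of their typical level and the 10 leading genes did not favour another type; clusters with hepatocyte markers at or above 0.5 of that level and fewer than 3 markers of another type were hepatocyte-like. Clusters whose 10 leading genes favoured another type were not called hepatocyte-like. These naming thresholds were set after the clusters had been seen. Cell names could differ from the authors' because they were rebuilt here.

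Each hepatocyte-like cell was scored as the mean z of log(1 + counts per 10000) of 10 pericentral landmark genes minus that of 10 periportal ones. The pericentral landmarks were Glul, Cyp2e1, Slc1a2, Gulo, Rgn, Akr1c6, Lect2, Aldh1a1, Csad and 1 that is not reported here, and the periportal ones Cyp2f2, Hal, Sds, Hsd17b13, Ctsc, Pck1, Aldh1b1, Cdh1, Hsd17b6 and Etnppl. Within each library, ranked cells were divided into 3 equal zones (pericentral, middle, periportal) and, for profiles, 10 rank bins. Landmarks were left out of all tests and lists. UMI counts were summed per mouse and zone into 12 sums of 4674540 to 7887790 UMIs and tested with edgeR 4.0.16 (filterByExpr, TMM factors, quasi-likelihood fit with zone and mouse as terms) in R 4.3.3, with Benjamini-Hochberg adjustment at 0.05. A middle-high or middle-low gene had to pass against both outer zones in the same direction. SE is the absolute log2 fold change divided by the square root of the F statistic. CPM means and per-mouse directions are on the TMM scale (pseudocount 1 CPM for per-mouse ratios). Sums of the same mouse come from the same animal, which pairs them: the lowest correlation of deviations from the zone means was 0.523 within a mouse and the highest between mice was 0.293, and mouse was a block in the main design.

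Gene lists were fixed before the data were examined and tested with camera of limma 3.58.1 at a preset correlation of 0.01, two-sided, with Benjamini-Hochberg adjustment over 27 lists: urea cycle, gluconeogenesis, amino acid catabolism, glycolysis and lipogenesis, fatty acid oxidation and ketogenesis, cholesterol synthesis, bile acid synthesis and transport, xenobiotic cytochrome P450, phase II conjugation, Wnt/beta-catenin targets, coagulation and fibrinolysis, apolipoproteins and lipoprotein assembly, complement, iron and hepcidin, IGF and growth factor receptors, mTOR and cyclin D, cell cycle, mitochondrially encoded, nuclear respiratory chain, ribosomal proteins, immediate early and dissociation, heat shock and unfolded protein response, acute phase, circadian clock, female-biased, male-biased and hypoxia targets. At the preset correlation 18 lists were called, and with a correlation estimated from the data 6: gluconeogenesis, bile acid, cytochrome P450, conjugation, Wnt/beta-catenin targets and male-biased genes each kept theirs. Lists with fewer than all members tested had the rest below the count filter.

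The genes named in the text followed a rule fixed at the same time: the 4 host genes; the 8 genes with the largest fold each way between the ends among those past the threshold, at a mean of at least 50 CPM and with 1 direction in 4 mice; up to 3 members per list with the largest absolute log2 fold change past the threshold, together with Igfbp2, Ccnd1 and Hamp; up to 6 middle-high and 6 middle-low genes at a mean of at least 50 CPM; and for each library the 3 highest and 3 lowest genes that stood apart. Landmarks were named only to describe the zones. Genes outside this rule are said to be so where they appear, and cluster genes only describe clusters. The same design fixed the cell filters, landmarks, tests and planned comparisons before the data were examined.

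Between lines no test was made, with 1 library each. Levels are UMIs of a gene over all UMIs of the cells in CPM, with exact 95% Poisson intervals; shares have exact (Clopper-Pearson) binomial intervals; log2 ratios of 2 levels have intervals from the counting error of both. All of these cover counting error only. A count of 0 was given the limit of 3 counts. A gene stood apart in a library when it lay at least 2-fold above or below each other library after adding 5 CPM, with the highest library at 50 CPM or more. List medians per library were compared with 10000 random lists of the same size drawn within 50 genes of each member's expression rank. For tdTomato shares, cells were also thinned to 2000 UMIs. RNA of lysed cells, doublets or misnamed cells can give tdTomato UMIs in other cell types, which was not measured, so the level in named other cell types of the same library is given beside each value. Multigene families (Hamp and Hamp2, Mup, Cyp2a, Cyp2c, Cyp3a, Saa, Sult2a and Gstm genes) can share or lose reads under unique counting, and their members are uncertain.

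Alternatives were DESeq2 1.42.0, RLE factors or total counts in place of TMM, no count filter, no replicate block, other limits on mitochondrial share, UMIs and doublet scores, all kept cells, narrower end zones, boundaries from the pooled cells, another score, the first or last 5 landmarks, thinning, leaving out each mouse and the carriers of a driver, estimated correlation and fry for lists, and other clustering resolutions. Chosen after seeing the data were fits without mitochondrially encoded genes, without clusters led by nuclear RNA and within each library pair, the zone by pair interaction, the comparison of library pairs, and tdTomato thinned or under another score. The zone test was tested on simulated data drawn from the real means and library sizes, with 10011 genes: of the genes changed 1.5-, 2- and 4-fold between the ends it recovered 70.1%, 89.6% and 100%, with 10 false calls among 9811 unchanged genes, and for a peak in the middle 65.7%, 82.1% and 98.5% with 0 false calls. The simulation of the zone test drew sums directly and ranked no cells by expression. Its false calls therefore leave out any effect of setting the zones by such a ranking. The list percentile step put 5.5% of 200 simulated lists outside the central 95%. The simulated lists held random genes, so this gives no error rate for lists whose members vary together. Other tools were Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.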

Results

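Single-cell transcriptomes were collected from the livers of 4 female mice, each of which carried a tamoxifen-inducible Cre recombinase (CreERT2) named for a liver gene together with a Rosa-LSL-tdTomato reporter. In such animals tamoxifen activates the recombinase in cells that use the driver, and those cells then make the red fluorescent protein tdTomato. The drivers were Cyp1a2-CreER, Gls2-CreER, Gls2-CreER and Oat-CreER together in 1 animal, and Hamp2-CreER, with 1 mouse and 1 library each. Tamoxifen was given at 6 to 10 weeks of age, and hepatocytes were isolated by collagenase perfusion 2 weeks later. The question the design poses is where along the liver lobule, from the central vein (pericentral) to the portal vein (periportal), each driver labels hepatocytes. Lines could not be tested against each other with 1 library each, so levels per line are given with intervals that cover counting error only. Zones were compared within mouse, with the 4 mice as replicates.

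The 4 libraries held 29549493, 30846331, 28366806 and 29544462 UMIs in the order Cyp1a2, Gls2, Gls2/Oat and Hamp2 line. The Cyp1a2 and Gls2 libraries each held 4000 cell barcodes with medians of 6788.5 and 6779.5 UMIs, and the Gls2/Oat and Hamp2 libraries each held 5000 with medians of 4071.5 and 4028.5 UMIs. The median share of UMIs from mitochondrially encoded genes was 26.5%, 30.2%, 17.8% and 19.9%. After filtering, 2329, 2411, 3935 and 3588 cells remained, 12263 in all. Below, the 4000-barcode pair means the Cyp1a2 and Gls2 libraries and the 5000-barcode pair means the Gls2/Oat and Hamp2 libraries.

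Hepatocyte-like cells, expressing genes such as Alb and Apoa1, made up 91.2% (95% exact binomial interval 89.9 to 92.3) of kept cells in the Cyp1a2 line, 88.1% (86.7 to 89.3) in the Gls2 line, 78.6% (77.3 to 79.8) in the Gls2/Oat line and 70.9% (69.4 to 72.4) in the Hamp2 line. Kupffer cell or macrophage-like cells, carrying C1qa, C1qb, Cd5l and Clec4f, came next with 1.46%, 2.90%, 5.67% and 3.96%. Endothelial-like cells took 0.129%, 0.166%, 1.45% and 1.25%, and stellate cell or fibroblast-like cells 0.472%, 0.788%, 1.19% and 0.864%. T or NK cell-like cells took 0.730%, 0.581%, 0.788% and 1.09%, monocyte or dendritic cell-like cells 0.172%, 0.622%, 1.07% and 1.14%, and B cell-like cells, led by immunoglobulin genes such as Igkc and Jchain, at most 0.472%. Clusters that stayed unnamed held 5.41%, 6.72%, 11.2% and 20.6% of cells. They were led by haemoglobin genes, by mixed endothelial and stellate genes, by the cholangiocyte genes Spp1, Epcam and Krt19, or by neutrophil and cell cycle genes. Clusters 9 and 14, led by haemoglobin genes, had hepatocyte markers at 0.79 and 1.66 of their typical level. Cluster 9 held 10, 25, 221 and 353 cells of the 4 libraries, and cluster 14 held 0, 0, 68 and 248. Counted as hepatocytes, they would raise the hepatocyte-like share most in the Gls2/Oat and Hamp2 lines. The hepatocyte-like class was held by different clusters in the 2 pairs: clusters 0, 3, 4, 5 and 13 came mostly from the 4000-barcode pair, clusters 1, 2, 12 and 21 from the Gls2/Oat library and clusters 6, 7, 8 and 16 from the Hamp2 library. Hepatocyte-like clusters with a nuclear RNA (Malat1, Neat1 or Xist) among their leading genes held 0.188%, 0.565%, 12.1% and 33.6% of hepatocyte-like cells. They are called clusters led by nuclear RNA below. Cluster 16 among them had Neat1 as a leading gene, but after the acute phase genes Saa1, Saa2 and Orm2. It held 248 of the 854 such cells of the Hamp2 library. Its median depth was 6848.5 UMIs, against 3177 and 2837.5 in clusters 8 and 12, the other such clusters. The perfusion, the number of barcodes kept and the rule for naming clusters can set the cell shares given here. With no limit on the mitochondrial share the hepatocyte-like shares were 84.0%, 82.3%, 81.1% and 74.0%.

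The 9883 hepatocyte-like cells were ranked within each library by 10 pericentral and 10 periportal landmark genes and divided into 3 equal zones. The landmarks describe the zones and are not results. Glul, the glutamine synthetase of perivenous hepatocytes, averaged 415 ± 132 CPM in the pericentral and 66.9 ± 42.4 CPM in the periportal zone (mean ± SD, n = 4 mice), and the periportal histidine ammonia-lyase gene Hal averaged 142 ± 69.5 and 800 ± 135 CPM. The score is continuous, and 284, 276, 375 and 356 cells of the 4 libraries lay within 0.1 SD of a zone boundary. The median mitochondrial share rose from the pericentral to the periportal zone in each library, from 16.2% to 20.6% in the Cyp1a2, 19.5% to 26.7% in the Gls2, 15.8% to 18.6% in the Gls2/Oat and 15.6% to 19.8% in the Hamp2 line.

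tdTomato mRNA was graded along this axis in opposite directions in the Cyp1a2 and Gls2 lines. In the Cyp1a2 line it stood at 391 CPM (95% Poisson interval 374 to 409) in the pericentral, 235 (222 to 248) in the middle and 53.8 (47.9 to 60.2) in the periportal zone, a 7.27-fold pericentral excess. In the Gls2 line it stood at 59.2 CPM (52.6 to 66.3), 181 (170 to 193) and 274 (261 to 288), a 4.64-fold periportal excess. The Gls2/Oat line had the highest and most even signal, with 970 CPM (948 to 992), 952 (927 to 977) and 1133 (1107 to 1159), and in 10 rank bins it ran from 1088 CPM in the most pericentral bin through 836 in bin 4 to 1235 in the most periportal bin. The Hamp2 line had the lowest signal, 110 CPM (102 to 118) in the pericentral, 50.9 (44.6 to 57.8) in the middle and 44.4 (39.0 to 50.4) in the periportal zone, with its highest bins at the pericentral end (120 CPM in bin 1 and 137 in bin 2).

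**Figure D1:**
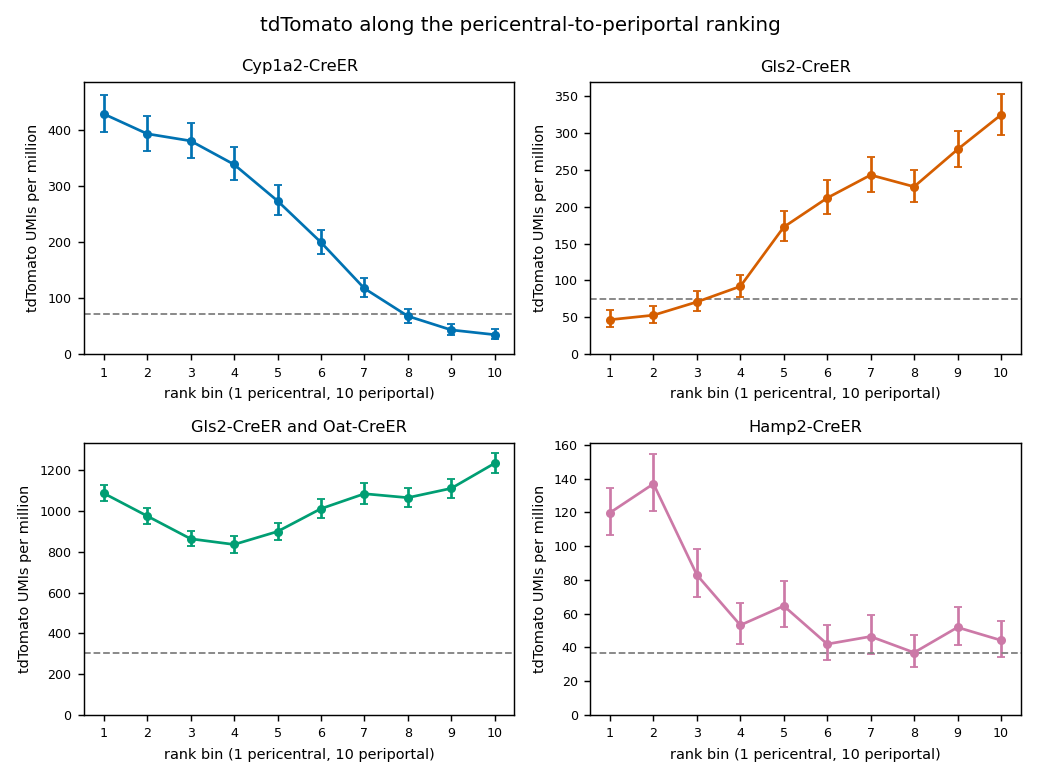
tdTomato level (CPM, vertical axis) in 10 equal rank bins of hepatocyte-like cells from the most pericentral (bin 1) to the most periportal (bin 10), 1 panel per library, with 95% Poisson intervals and a dashed line at the level in the named other cell types of the same library. The level falls from 429 to 34.3 in the Cyp1a2 line, rises from 46.4 to 325 in the Gls2 line, stays between 836 and 1235 in the Gls2/Oat line, and in the Hamp2 line falls from 120 in bin 1 to 44.1 in bin 10.

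tdTomato was also counted outside hepatocyte-like cells. Whether named other cell types use these drivers was not tested. In these cell types tdTomato stood at 70.8 CPM (50.1 to 97.2) in 80 cells of the Cyp1a2 line and 74.5 (57.0 to 95.7) in 126 of the Gls2 line. It stood at 304 (279 to 331) in 401 of the Gls2/Oat line and 36.4 (27.3 to 47.6) in 304 of the Hamp2 line. The log2 ratio to the other cell types had an interval that reached 0 or below in the periportal zone of the Cyp1a2 line (-0.40, -0.88 to 0.089), the pericentral zone of the Gls2 line (-0.33, -0.73 to 0.065) and the periportal zone of the Hamp2 line (0.29, -0.14 to 0.72). In the middle zone of the Hamp2 line it was 0.48 (0.054 to 0.91). At least 1 tdTomato UMI was seen in 87.4%, 65.6% and 27.97% of pericentral, middle and periportal cells of the Cyp1a2 line, against 33.8% of its other cells (median depths 6696.5, 6677, 7058.5 and 6371 UMIs). In the Gls2 line the shares were 30.9%, 61.8% and 77.8%, against 33.3% (6504, 6669, 7205 and 5625.5 UMIs). The Gls2/Oat line had 91.0%, 87.5% and 93.5%, against 70.8% (5392, 3907, 4560 and 3794 UMIs), and the Hamp2 line 25.9%, 17.4% and 18.2%, against 15.1% (5000, 3617, 4227.5 and 3788 UMIs). With each cell thinned to 2000 UMIs, which left out 0 cells, the zone shares became 53.0%, 34.7% and 9.75% in the Cyp1a2, 11.6%, 31.5% and 41.5% in the Gls2, 77.1%, 75.05% and 83.2% in the Gls2/Oat and 12.4%, 9.31% and 8.25% in the Hamp2 line. Cells with at least 3 tdTomato UMIs had a median rank of 27.0 on a scale from 0 (pericentral) to 100 (periportal) in the Cyp1a2 line (581 cells), 73.8 in the Gls2 line (445), 49.9 in the Gls2/Oat line (2117) and 20.6 in the Hamp2 line (101). A second transgene feature, wpre, had 0 UMIs in all 4 libraries, which allows up to 0.102, 0.0973, 0.106 and 0.102 CPM.

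The genes for which the drivers are named differed in their own position. Oat (ENSMUSG00000030934, mm10 chromosome 7, 132557478 to 132576398), which encodes ornithine aminotransferase, was high at the pericentral end, at 894 ± 535 CPM in the pericentral and 49.6 ± 18.5 CPM in the periportal zone (SD, n = 4 mice), a log2 fold change of 4.06 ± 0.14 (SE). Cyp1a2 (ENSMUSG00000032310, chromosome 9, 57676937 to 57683703), a drug-metabolising cytochrome P450, was at 426 ± 73.5 against 48.1 ± 17.9 CPM, a log2 fold change of 3.19 ± 0.11. Gls2 (ENSMUSG00000044005, chromosome 10, 128194457 to 128210004), the liver glutaminase, was at 98.8 ± 39.6 against 353 ± 94.7 CPM, a log2 fold change of -1.84 ± 0.15. Each of the 3 had its direction in 4 of 4 mice, with adjusted p of 1.16e-14 for Oat, 1.7e-14 for Cyp1a2 and 4.93e-09 for Gls2 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Without the mice carrying a driver at the gene, the Cyp1a2 log2 fold change was 3.09, the Gls2 log2 fold change -2.07 and the Oat log2 fold change 4.22.

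Hamp2 (ENSMUSG00000056978, chromosome 7, 30922372 to 30924681), a paralog of the hepcidin gene Hamp, gave no call between the ends: its log2 fold change was -0.16 ± 0.22, and it was higher periportally in 2 of 4 mice (adjusted p = 0.634, edgeR's quasi-likelihood test). It averaged 927 ± 680 CPM in the pericentral and 1590.2 ± 1717 CPM in the periportal zone. The libraries went opposite ways. Without TMM factors the log2 ratio of pericentral to periportal CPM was -0.74 (95% interval -0.79 to -0.69) in the Cyp1a2 and -0.63 (-0.66 to -0.59) in the Gls2 line. It was 0.88 (0.81 to 0.94) in the Gls2/Oat and 0.80 (0.70 to 0.91) in the Hamp2 line. On the TMM scale the ratios were -1.12, -1.05, 0.76 and 0.65 in the same order. The peak bins of Hamp2 were 8 and 7 in the 4000-barcode pair and 2 in both libraries of the 5000-barcode pair. A zone by pair interaction, chosen after these values were seen, was 1.80 ± 0.08 on the log2 scale (adjusted p = 6.94e-26, edgeR's quasi-likelihood test). Leaving out the Cyp1a2 mouse or the Gls2 mouse turned the sign of the Hamp2 log2 fold change, to 0.16 and 0.14. Hamp itself was higher periportally in 4 of 4 mice, at 949 ± 325 against 1669 ± 513 CPM (log2 fold change -0.84 ± 0.13, adjusted p = 2.33e-05, edgeR's quasi-likelihood test). Hamp peaked in bins 8, 8, 7 and 9 of the Cyp1a2, Gls2, Gls2/Oat and Hamp2 lines, with its lowest level in bin 10 of the Gls2/Oat line. On the TMM scale the log2 ratio of Hamp was only -0.14 in the Gls2/Oat line, against -1.36, -1.14 and -0.76 in the Cyp1a2, Gls2 and Hamp2 lines. Reads shared by Hamp and Hamp2 leave both uncertain.

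**Figure D2:**
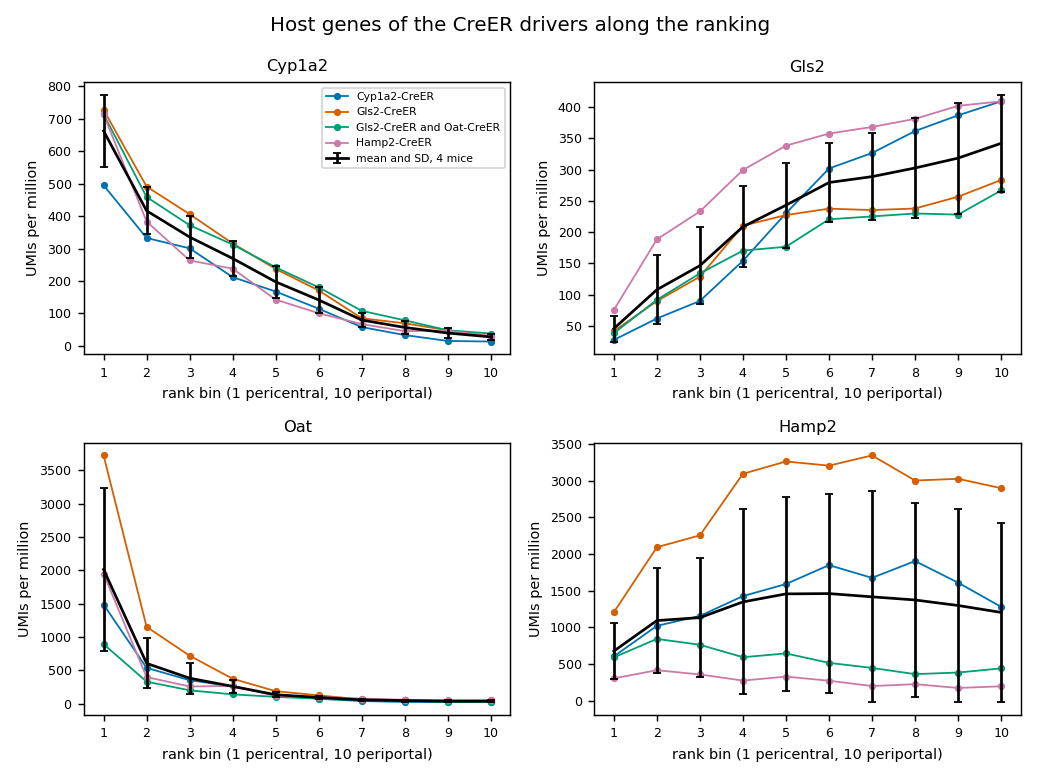
CPM (vertical axis) of Cyp1a2, Gls2, Oat and Hamp2 in 10 equal rank bins from pericentral (1) to periportal (10), with 1 coloured line per library and the mean and SD of the 4 mice in black. Cyp1a2 falls from a mean of 663 ± 112 in bin 1 to 27.5 ± 10.4 in bin 10 and Gls2 rises from 45.7 ± 20.7 in bin 1, whereas Hamp2 peaks in bins 8 and 7 of the 4000-barcode pair and in bin 2 of the 5000-barcode pair, so that its SD bars reach below 0.

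Among genes outside the landmarks with a mean of at least 50 CPM and 1 direction in 4 of 4 mice, the steepest pericentral excess after Oat was that of Cyp2a5 (3.67 ± 0.14, log2 fold change ± SE; 335 ± 168 against 24.3 ± 3.71 CPM). It was followed by Cyp1a2, the sulfotransferase gene Sult3a1 (2.97 ± 0.25; 226 ± 261 against 46.3 ± 81.0 CPM), Cyp7a1, which encodes the rate-limiting enzyme of bile acid synthesis (2.87 ± 0.09), Cyp2c50 (2.44 ± 0.12; 767 ± 341 against 154 ± 94.3 CPM), the fatty aldehyde dehydrogenase gene Aldh3a2 (2.002 ± 0.14) and Cyp2c69 (1.94 ± 0.10). Among the same genes the steepest periportal excess was that of Ptgds, which encodes a prostaglandin D synthase (-3.98 ± 0.19; 13.3 ± 10.5 against 194 ± 90.6 CPM), ahead of the amino acid transporter gene Slc3a1 (-2.87 ± 0.20), the steroid hydroxylase gene Cyp17a1 (-2.56 ± 0.19), Cyp2a4 (-2.13 ± 0.12), Gls2, the acute phase gene Saa1 (-1.78 ± 0.20), the mitochondrial serine transporter gene Sfxn1 (-1.74 ± 0.11) and the apolipoprotein gene Apoa4 (-1.72 ± 0.10). All of these had an adjusted p of at most 8.46e-07 (edgeR's quasi-likelihood test), and Cyp2a5 and Cyp2a4, the Cyp2c genes and Saa1 have close paralogs that may share reads.

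Of 10011 genes tested by edgeR's quasi-likelihood test with mouse as a block, there were 1561 genes higher pericentral and 1670 genes higher periportal at an adjusted p below 0.05. Of these, 172 and 228 differed at least 2-fold. Of these 3231 genes, 2995 had their direction in 4 of 4 mice. The split depended on the scaling: with total counts in place of TMM factors the median of all genes moved up by 0.25 on the log2 scale and the calls became 3846 and 662, so that 85.3% instead of 48.3% were pericentral. Changes are given here relative to the TMM scale. The zones were set from the expression of the same cells, and in 4 of 20 rankings by random genes as many genes were called at any fold, whereas the highest count at least 2-fold was 299 against 400 with the landmarks. The gene lists below were not run under such rankings. Their counts and tests therefore cannot tell a difference by zone from one along any expression ranking. Landmarks left out of the Wnt/beta-catenin list (Glul and Slc1a2) and the gluconeogenesis list (Pck1) helped to set the zones.

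Most called genes of xenobiotic and bile acid metabolism were pericentral. Of 18 tested xenobiotic cytochrome P450 genes, 13 were higher pericentrally, 3 periportally and 2 did not pass, with 13 and 3 adjusted over the list alone. Besides Cyp1a2, Cyp2a5 and Cyp2c50 these set a list median of 0.89 on the log2 scale (camera, adjusted p = 1.19e-26; adjusted p = 0.00647 with an estimated correlation). Of 16 phase II conjugation genes, which encode enzymes that couple drugs and electrophiles to glutathione, sugars or sulfate, 9 were pericentral, 2 periportal and 5 did not pass, with 9 and 2 adjusted over the list alone. The glutathione transferase genes Gstm3 (3.37 ± 0.15), Gstm2 (3.28 ± 0.12) and Gstm6 (1.43 ± 0.08) led it. The median was 0.32 (camera, adjusted p = 2.1e-15; adjusted p = 0.0303 with an estimated correlation). Of 15 bile acid synthesis and transport genes, 7 were pericentral, 2 periportal and 6 did not pass, and adjusted over the list alone the counts were 8 and 2. Beside Cyp7a1 they included Cyp7b1 (2.71 ± 0.15) and Cyp8b1 (1.11 ± 0.13), which encode further sterol hydroxylases. The median was 0.16 (camera, adjusted p = 1.14e-08; adjusted p = 0.00973 with an estimated correlation). All 9 tested Wnt/beta-catenin targets outside the landmarks were pericentral, also adjusted over the list alone, at low levels: Slc13a3 (3.84 ± 0.24), the R-spondin receptor gene Lgr5 (3.79 ± 0.30; 7.34 ± 1.71 against 0.489 ± 0.167 CPM) and Axin2 (3.49 ± 0.32), with a list median of 2.33 (camera, adjusted p = 8.51e-17; adjusted p = 0.0105 with an estimated correlation).

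Most called genes of nitrogen and glucose metabolism were periportal. Of 9 gluconeogenesis genes, 8 were periportal and 1 pericentral, also adjusted over the list alone; Ppargc1a, the coactivator of the fasting programme (-0.95 ± 0.08), Slc37a4, the glucose-6-phosphate transporter gene (-0.84 ± 0.06), and Fbp1 (-0.74 ± 0.07) led them. The median was -0.43 (camera, adjusted p = 3.88e-07; adjusted p = 0.0105 with an estimated correlation). Of 8 urea cycle genes, 5 were periportal, among them Asl (-0.74 ± 0.08), Ass1 (-0.56 ± 0.08) and Arg1 (-0.49 ± 0.08), 2 were pericentral and 1 did not pass, with 5 and 2 adjusted over the list alone. The list as a whole gave no call (median -0.23 and 0.04 with total counts; camera, adjusted p = 0.0523; adjusted p = 0.309 with an estimated correlation), although it did without the Gls2/Oat or the Hamp2 mouse. Of 20 amino acid catabolism genes, 11 were periportal, 6 pericentral and 3 did not pass, with 11 and 6 adjusted over the list alone; Gls2 and the serine dehydratase-like gene Sdsl (-2.42 ± 0.20) stood against Oat. The list median was -0.22, but 0.05 with total counts (camera, adjusted p = 0.0177; adjusted p = 0.221 with an estimated correlation), and without the Gls2 mouse the amino acid catabolism list, at a median of -0.20, gave no call. Of 14 glycolysis and lipogenesis genes, 9 were periportal, 2 pericentral and 3 did not pass, with 9 and 2 adjusted over the list alone. Pnpla3 (-1.67 ± 0.21), the ATP citrate lyase gene Acly (-0.86 ± 0.10) and Srebf1, a master regulator of lipogenesis (-0.73 ± 0.07), were among the periportal genes. The median was -0.31 (camera, adjusted p = 0.00259; adjusted p = 0.191 with an estimated correlation). This call was lost with total counts, where the glycolysis and lipogenesis list had a median of -0.04.

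Lipid lists were mixed. Of 16 fatty acid oxidation and ketogenesis genes, 7 were pericentral, 1 periportal and 8 did not pass, with 7 and 1 adjusted over the list alone, led by Acaa1b (0.61 ± 0.08). The list median was 0.15 (camera, adjusted p = 0.00643; adjusted p = 0.191 with an estimated correlation). Of 14 cholesterol synthesis genes, 6 were pericentral, among them Hmgcs1 (0.99 ± 0.10), Idi1 (0.84 ± 0.09) and Msmo1 (0.57 ± 0.09), 5 were periportal and 3 did not pass. Adjusted over the list alone, the counts were 7 and 6. They gave no call as a list, except without the Cyp1a2 mouse. The median was 0.24 (camera, adjusted p = 0.224; adjusted p = 0.666 with an estimated correlation). Of 14 apolipoprotein and lipoprotein assembly genes, 11 were periportal and 3 did not pass, with 13 periportal adjusted over the list alone. Apoa4, Apoc3, whose product slows triglyceride clearance (-1.15 ± 0.14), and Apoa5 (-0.63 ± 0.09) led it. The median was -0.39 (camera, adjusted p = 2.18e-07; adjusted p = 0.229 with an estimated correlation).

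Most genes of secreted plasma proteins were higher periportally. Of 17 coagulation and fibrinolysis genes, 15 were periportal and 2 did not pass, also adjusted over the list alone, led by the antithrombin gene Serpinc1 (-0.87 ± 0.11), F7 (-0.79 ± 0.08) and the kininogen gene Kng1 (-0.78 ± 0.11). The median was -0.56 (camera, adjusted p = 4.13e-09; adjusted p = 0.223 with an estimated correlation). Of 17 complement genes, 13 were periportal, such as Cfb (-0.85 ± 0.11) and C3 (-0.84 ± 0.11), 1 was pericentral and 3 did not pass, with 13 and 1 adjusted over the list alone. The median was -0.48 (camera, adjusted p = 2.5e-06; adjusted p = 0.223 with an estimated correlation). The pericentral one, C6 (0.92 ± 0.31), averaged 3.63 CPM or less, and the C6 log2 fold change was 0.60 without the Cyp1a2 mouse and 0.82 without the Gls2 mouse, in neither case past the threshold. Of 15 acute phase genes, 13 were periportal and 2 did not pass, also adjusted over the list alone. Beside Saa1 these included the lipocalin gene Lcn2 (-1.63 ± 0.13) and Saa2 (-1.50 ± 0.36). The median was -0.54 (camera, adjusted p = 1.42e-08; adjusted p = 0.174 with an estimated correlation). Of 18 iron and hepcidin genes, 10 were periportal, 2 pericentral and 6 did not pass, with 10 and 2 adjusted over the list alone. Hpx, which encodes the haem scavenger hemopexin (-1.38 ± 0.15), Hamp and the iron exporter gene Slc40a1 (-0.76 ± 0.07) led it. The median was -0.29 (camera, adjusted p = 0.000788; adjusted p = 0.223 with an estimated correlation). With at most 20% mitochondrial UMIs the complement list, at a median of -0.21, was no longer called. The periportal zone also had the higher mitochondrial share given above. Some of these differences were smaller in the 5000-barcode pair. In the Cyp1a2, Gls2, Gls2/Oat and Hamp2 lines the log2 ratios were -1.21, -1.21, -0.48 and -0.46 for C3 and -1.86, -2.09, -0.84 and -0.79 for Hpx, with zone by pair interactions of 0.74 ± 0.07 and 1.15 ± 0.08 (adjusted p = 7.3e-12 and 9.52e-18, edgeR's quasi-likelihood test), and Serpinc1 and Kng1 were alike. The nuclear RNA Malat1 (-1.35), named after its value was seen, was periportal too.

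**Figure D3:**
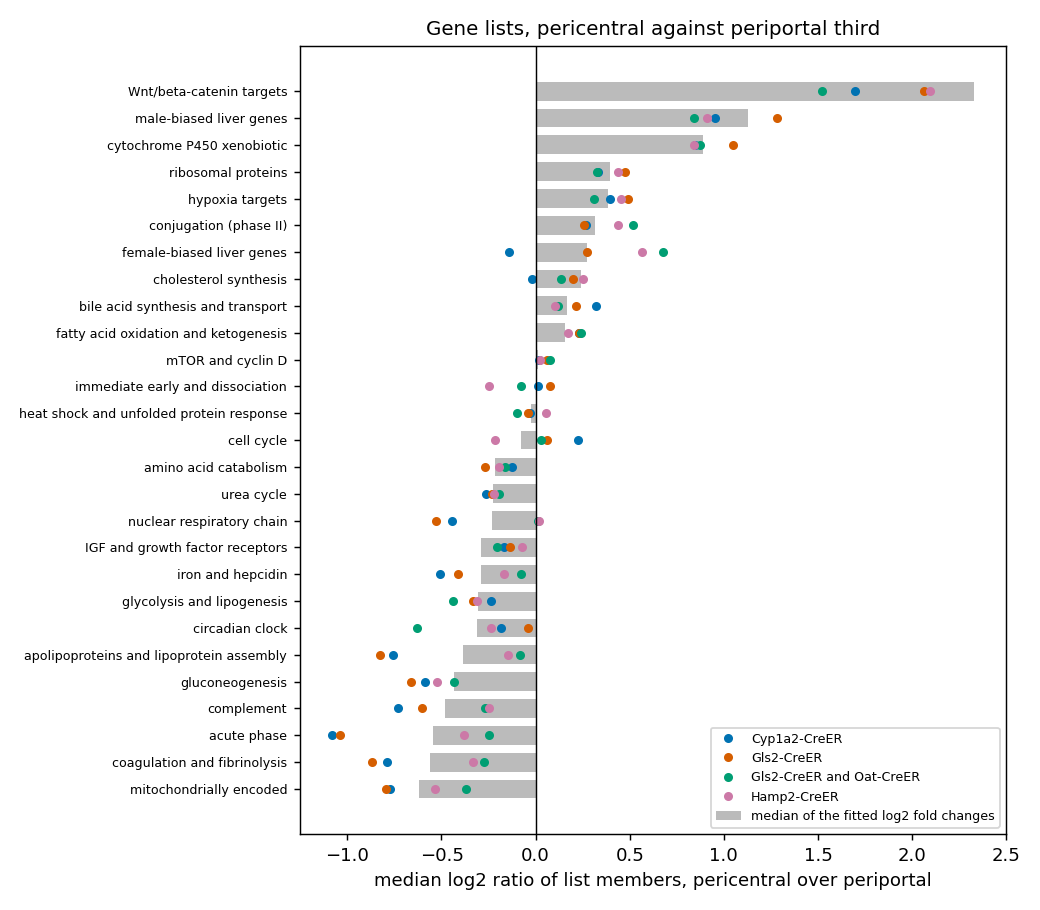
Median log2 ratio of pericentral to periportal level (horizontal axis) of the tested members of each of 27 gene lists, with grey bars for the fitted values over 4 mice and dots for the ratios of CPM plus 1 within each library. The Wnt/beta-catenin targets have the highest median (2.33) and the mitochondrially encoded genes the lowest (-0.62); dots lie nearer 0 than the bar for lists of low-expressed genes.

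All 13 mitochondrially encoded genes were periportal, also adjusted over the list alone, led by mt-Nd6 (-1.09 ± 0.11), mt-Co2 (-0.85 ± 0.10) and mt-Atp6 (-0.76 ± 0.11). The median was -0.62 (camera, adjusted p = 1.59e-12; adjusted p = 0.188 with an estimated correlation). The mitochondrial share of all UMIs was higher periportally too. With at most 20% mitochondrial UMIs per cell the mitochondrially encoded list, at a median of -0.11, was no longer called. That limit caps the level of these same genes in each cell, so the lost call cannot decide whether they differ between zones. Of 28 nuclear genes of the respiratory chain, 13 were periportal, such as Ndufa1 (-0.66 ± 0.09), Ndufa4 (-0.56 ± 0.12) and Cox5b (-0.52 ± 0.11), and 15 did not pass, with 14 periportal adjusted over the list alone. Ndufa4 (-0.08 and -0.13) and Cox5b (-0.16 and -0.10) differed little in the Gls2/Oat and Hamp2 lines. The median was -0.23, but 0.02 with total counts, where the call was lost (camera, adjusted p = 0.00161; adjusted p = 0.536 with an estimated correlation). Ribosomal protein genes went the other way: 31 of 32 were pericentral and 1 did not pass, with 32 adjusted over the list alone. They included Rps19 (0.61 ± 0.08), Rpl35 (0.60 ± 0.08) and Rpl37 (0.59 ± 0.08). The median was 0.39 (camera, adjusted p = 1.68e-12; adjusted p = 0.232 with an estimated correlation).

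Growth-related genes did not move together. Ccnd1, the cyclin that carries cells through G1, was higher pericentrally in 4 of 4 mice, at 273 ± 77.5 against 88.5 ± 28.7 CPM (1.65 ± 0.14, adjusted p = 1.17e-08, edgeR's quasi-likelihood test). It peaked in rank bin 5 in the Cyp1a2 line and bin 3 in the Gls2 line. In the Gls2/Oat and Hamp2 lines the peak was in bin 1. Igfbp2, an IGF-binding protein gene, was lower in the pericentral zone in 4 of 4 mice (238 ± 67.9 CPM, against 404 in the middle and 389 ± 150 in the periportal zone; -0.67 ± 0.15; adjusted p = 0.00125, edgeR's quasi-likelihood test), and its highest rank bins were 6, 6, 5 and 6 of 10. It exceeded the pericentral zone in the middle by 0.76 ± 0.15 on the log2 scale (adjusted p = 0.00115, edgeR's quasi-likelihood test) but the periportal zone by only 0.08, so it was not called a middle-high gene. The difference between the ends came mostly from the 4000-barcode pair: the log2 ratios per mouse were -1.29, -1.24, -0.22 and -0.02 in the Cyp1a2, Gls2, Gls2/Oat and Hamp2 lines, and within the 5000-barcode pair the Igfbp2 log2 fold change was not past the threshold. The zone by pair interaction for Igfbp2 was 1.15 ± 0.10 (adjusted p = 3.74e-14, edgeR's quasi-likelihood test). Of 13 IGF and growth factor receptor genes, 6 were periportal, among them Igfals (-0.57 ± 0.09), 2 pericentral, among them Igfbp1 (0.61 ± 0.08), and 5 did not pass. Adjusted over the list alone, the counts were 7 and 3. The median was -0.29 (camera, adjusted p = 0.241; adjusted p = 0.309 with an estimated correlation). Of 16 mTOR and cyclin D genes, 4 were pericentral, among them Cdk6 (0.88 ± 0.09), 2 periportal and 10 did not pass, with 4 and 2 adjusted over the list alone. The median was 0.01 (camera, adjusted p = 0.164; adjusted p = 0.232 with an estimated correlation). Of 5 tested cell cycle genes, the replication gene Mcm6 (0.93 ± 0.24) was pericentral, Birc5 (-1.25 ± 0.36) periportal and 3 did not pass, also adjusted over the list alone. Birc5 averaged 1.43 CPM, was not past the threshold by DESeq2, over all kept cells (Birc5 log2 fold change -0.51), without the block or within the 5000-barcode pair, and was not tested without the Gls2/Oat or the Hamp2 mouse. The cell cycle list had a median of -0.08 and a mean of -0.13 while camera's direction was pericentral (adjusted p = 0.994, and adjusted p = 0.994 with an estimated correlation).

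Of 7 hypoxia targets, 5 were pericentral, 1 periportal and 1 did not pass, also adjusted over the list alone, led by Ndrg1 (2.69 ± 0.27), the prolyl hydroxylase gene Egln3 (1.70 ± 0.18) and the glycolytic regulator gene Pfkfb3 (1.42 ± 0.13). The median was 0.38 (camera, adjusted p = 0.000144; adjusted p = 0.105 with an estimated correlation). Of 6 male-biased liver genes, 4 were pericentral, 1 periportal and 1 did not pass, also adjusted over the list alone. The pericentral ones included Elovl3 (5.24 ± 0.73), which averaged only 1.08 CPM, Cyp7b1 and Cyp2d9 (1.47 ± 0.13). Cyp7b1 is also in the bile acid list and Cyp2d9 in the cytochrome P450 list, so the calls of these lists are not independent. The median of the male-biased list was 1.13 (camera, adjusted p = 1.41e-06; adjusted p = 0.0117 with an estimated correlation). Of 11 female-biased genes, 5 were pericentral, among them Sult3a1, 3 periportal, among them Cyp2a4, and 3 did not pass. Adjusted over the list alone, the counts were 7 and 3. The median was 0.27 (camera, adjusted p = 0.431; adjusted p = 0.676 with an estimated correlation). Of 12 circadian clock genes, 5 were periportal, among them Ciart (-0.70 ± 0.11) and Per3 (-0.64 ± 0.11), Nr1d1 (0.51 ± 0.09) was pericentral and 6 did not pass, with 6 and 1 adjusted over the list alone. The median was -0.31 (camera, adjusted p = 0.0682; adjusted p = 0.556 with an estimated correlation). This list was called without the Gls2 mouse. Of 16 immediate early and dissociation genes, 4 were periportal, among them Btg2 (-0.90 ± 0.09) and, except with total counts, Jund (-0.40 ± 0.07), 3 pericentral and 9 did not pass, with 5 and 3 adjusted over the list alone; the median was 0.01, the mean -0.01 and camera's direction periportal (adjusted p = 0.542; adjusted p = 0.850 with an estimated correlation). Of the pericentral ones, Klf6 (0.49 ± 0.19) was higher in 3 of 4 mice, and the Klf6 log2 fold change was 0.56 without the Gls2/Oat mouse and 0.14 without the Hamp2 mouse, in neither case past the threshold. Of 16 heat shock and unfolded protein response genes, 6 were pericentral, such as Hspb1 (0.90 ± 0.19) and Hspa1b (0.84 ± 0.17), 5 periportal, such as Herpud1 (-0.43 ± 0.07), and 5 did not pass, with 6 and 6 adjusted over the list alone; the median was -0.02, the mean 0.05 and camera's direction periportal (adjusted p = 0.887; adjusted p = 0.965 with an estimated correlation).

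The count of genes that peaked in the middle zone depended on the settings. Sult2a1, a hydroxysteroid sulfotransferase gene with close paralogs, was at 149 ± 139 CPM in the pericentral, 192 ± 147 in the middle and 109 ± 97.2 in the periportal zone (SD, n = 4). Its middle level exceeded the pericentral one by 0.51 ± 0.14 and the periportal one by 0.85 ± 0.14 on the log2 scale (adjusted p = 0.0146 and 0.00071, edgeR's quasi-likelihood test). Chd3 (0.26 ± 0.09 and 0.49 ± 0.09), Fam35a (0.27 ± 0.08 and 0.31 ± 0.08) and the NF-kB kinase gene Ikbkb (0.26 ± 0.07 and 0.25 ± 0.07) also met both tests. The full count was 6 middle-high genes and 1 middle-low gene; the remaining ones, Ugt1a5 and Nav2 (high) and the fatty acid transporter gene Cd36 (low; -0.95 ± 0.15 and -0.81 ± 0.15, mean 17.1 CPM), were below 50 CPM and are named after their values were seen. The middle-high count rested on the libraries used: it was 12 without the Cyp1a2 mouse, 1 without the Gls2/Oat mouse and 0 without the Hamp2 mouse, and it was 0 by DESeq2 and 1 without the clusters led by nuclear RNA. It rose to 19 with no count filter, 55 within the 5000-barcode pair and 142 with no limit on the mitochondrial share. The middle-low count was 2 without the Cyp1a2, the Gls2 or the Hamp2 mouse.

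Over all hepatocyte-like cells, each host gene was lowest in the line or lines that carry a driver named for it. Cyp1a2 stood at 167 CPM (160 to 173) in the Cyp1a2 line and at 242, 279 and 233 CPM in the Gls2, Gls2/Oat and Hamp2 lines. Gls2 stood at 200 (193 to 207) and 170 (164 to 176) CPM in its carriers, the Gls2 and Gls2/Oat lines, and at 242 and 291 CPM in the others. Single zones went otherwise for Gls2, Cyp1a2 and Oat. In the pericentral zone Gls2 was lowest in the Cyp1a2 line, at 67.8 CPM (60.8 to 75.4) against 101 and 93.1 CPM in its carriers. In the middle zone Cyp1a2 was at 130 CPM (120 to 141) in the Hamp2 line and 133 (124 to 144) in its carrier. In the periportal zone Oat was at 28.6 CPM (24.3 to 33.3) in the Cyp1a2 line and 36.5 (32.0 to 41.5) in its carrier, the Gls2/Oat line. Oat stood at 221 (214 to 227) CPM in the Gls2/Oat line and at 282, 587 and 422 CPM in the Cyp1a2, Gls2 and Hamp2 lines. Hamp2 stood at 279 (271 to 287) CPM in the Hamp2 line and at 1426, 2776 and 572 CPM in the Cyp1a2, Gls2 and Gls2/Oat lines. The log2 ratio of carriers to the others was -0.58 (-0.64 to -0.52) for Cyp1a2, -0.51 (-0.56 to -0.47) for Gls2, -0.95 (-0.996 to -0.903) for Oat and -2.49 (-2.54 to -2.45) for Hamp2, at percentiles 3.8, 4.2, 2 and 0 of genes of like expression compared between the same libraries. Hamp2 was also among the genes that set the library pairs apart, and against the other library of its own pair the log2 ratio was -1.02. With 1 mouse per line these differences have no replicate check.

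Hepatocytes of single libraries also stood apart in metabolic genes, again without a replicate check. By a fixed rule of size (at least 2-fold from each other library), 50 genes stood apart in at least 1 library, and 2 of them, Sult2a1 and Erdr1, in 2 libraries. In the Cyp1a2 line the organic anion transporter gene Slco1a1 was at 139 CPM against 3.29 to 20.4 elsewhere and Gm10709 at 92.8 against 0.649 to 1.15, while Sult2a1 was at 20.5 against 91.2 to 358 CPM. In the Gls2 line the lipogenic genes Acss2 (387 against 112 to 125 CPM) and Acly (566 against 166 to 277 CPM) were higher, and Cyp4a14 (36.5 against 270 to 670 CPM) and Cyp4a10 (136 against 352 to 762 CPM), which encode fatty acid omega-hydroxylases, were lower. In the Gls2/Oat line the carboxylesterase gene Ces1b was higher (312 against 63.0 to 73.5 CPM), and Alas1, the first enzyme of haem synthesis, was lower (65.7 against 182 to 192 CPM). In the Hamp2 line Sult3a1 (409 against 33.1 to 60.8 CPM) and the nuclear RNA Neat1 (3290 against 433 to 1015 CPM) were higher, and Mug2 (29.6 against 209 to 230 CPM), Hmgcs1 (149 against 342 to 436 CPM) and Hamp2 were lower. The glycolysis and lipogenesis list had medians of 0.20, 0.88, -0.96 and -0.48 relative to the mean of the other libraries on the log2 scale, at percentiles 99.9, 100, 0 and 0 of 10000 random lists matched on expression. The acute phase list had medians of -0.59, -0.77, 0.33 and 0.64, at percentiles 0, 0, 99.97 and 100. The signs of both lists follow the library pairs, which also differ in depth and in the share of cells in clusters led by nuclear RNA (0.188%, 0.565%, 12.1% and 33.6%). Members of a list can vary together between mice, which random lists do not copy. The percentiles can therefore overstate how far a list stands out.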

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

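Of the tests in this part, the comparison without clusters led by nuclear RNA and the comparison of carriers with the other library of their pair, made once the carriers were known to be lowest, were chosen after the result was seen. The fatty acid oxidation and ketogenesis list had a median log2 ratio of pericentral to periportal level of 0.17 in the Hamp2 line, against 0.23 to 0.24 in the other 3 libraries. The xenobiotic cytochrome P450 list had a median of 1.05 in the Gls2 line, against 0.84 to 0.87 in the other 3. Both stood out because 1 mouse lay far from the other 3 relative to their whole range, which chance gives in about 1 of 20 such sets; 2 of 112 sets did so, where chance would give 5.6.

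The tdTomato ratio of pericentral to periportal level spanned 5.07 on the log2 scale between lines, from -2.21 in the Gls2 line to 2.86 in the Cyp1a2 line. It stood out because lines went opposite ways, and the difference between lines was not tested, with 1 mouse each. Without TMM factors the Hamp2 ratio spanned 1.61, from -0.74 in the Cyp1a2 line to 0.88 in the Gls2/Oat line. It stood out for the same reason, likewise with no test between lines.

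The opposite Hamp2 slope between library pairs was set against 3 technical explanations. Depth differing along the axis was tested by thinning each cell to 2000 UMIs and ranking again. The log2 ratio without TMM factors then fell from 0.88 to 0.54 in the Gls2/Oat and from 0.80 to 0.55 in the Hamp2 line. The lower of the bounds in the 5000-barcode pair was 0.34, above 0. This argues against uneven UMI counts in the ranking and weight of cells as the whole cause. It cannot decide about other differences between deep and shallow cells, which thinning leaves in place. Another test argues against clusters led by nuclear RNA, frequent in the 5000-barcode pair, as the whole cause, since without them the lower of the bounds was 0.75. For the choice of landmarks, 3 of 3 other landmark settings kept opposite signs in the pairs. All 3 used the same landmark genes, in part or under another score. They cannot tell whether a different set of landmarks would keep these signs. The library pair and the line cannot be told apart here, and reads shared with Hamp were not tested. A biological difference between the lines stays open and untested.

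Each host gene was lower in its own line over all hepatocyte-like cells, though not Gls2 in the pericentral, Cyp1a2 in the middle or Oat in the periportal zone. The lower level was weighed against general differences between libraries and against the library pair. All 4 host genes lay below the 5th percentile of genes of like expression in the same comparison of libraries, which argues against general differences between libraries as the whole cause. Those genes were not matched on how much they vary between mice. Among the lines without the driver, Oat ran from 282 to 587 CPM and Hamp2 from 572 to 2776 CPM. Against the other library of the pair, 4 of 5 ratios lay below the 5th percentile of such genes, but Gls2 in the Gls2 line (-0.27) lay at percentile 16.4, so the library pair stays open. The labels do not say whether a driver is inserted at its host gene, so no effect of the driver on that gene was tested, and single mice could differ in these genes for other reasons.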

How the results depend on the processing

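Settings within library pairs, without clusters led by nuclear RNA, without mitochondrially encoded genes, and tdTomato thinned or rescored were chosen after seeing the data; the others were planned. Of 85 named genes, 40 kept their call between the ends under every alternative and 71 under every one except the fit without the block; 3 turned direction in any. Of the 3202 alternative values, named genes gave 2003 with the same call, 82 weaker, 1 stronger and 6 reversed, gene lists 625, 25, 25 and 25, middle genes 39 with the same call, 56 weaker and 5 reversed, and other values 237 within their spread and 73 outside it. In 34 pairs of gene and setting the gene was not tested. A minimum of 2000 UMIs removed no cell and so tested nothing. The cause was not tested for any change given here unless one is named.

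Genes higher pericentral, 1561, numbered 1016 by DESeq2, 3846 with total counts, 937 at a mitochondrial share of at most 20% and 726 after thinning. The count of genes higher periportal, 1670, became 662 with total counts and 840 after thinning. At least 2-fold, the counts of 172 and 228 became 289 and 133 with total counts and 110 and 112 after thinning. Total counts moved the median of all genes by 0.25. Without the replicate block, which leaves the differences between mice in the spread, 192 and 224 genes passed, 90 and 100 of them at least 2-fold, no middle-high (0) or middle-low (0) gene passed, and the glycolysis and lipogenesis list lost its call; 44 named genes lost theirs, while Cyp1a2, Gls2 and Oat kept theirs. The block changed no other call beyond those given. Leaving out each mouse, the counts ran from 1203 to 1303 pericentral and from 1368 to 1407 periportal.

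Middle-high genes, 6, numbered 0 by DESeq2, 19 with no count filter, 0 at a mitochondrial share of at most 20%, 142 with no such limit, 2119 over all kept cells, 0 with the UMI ratio score, 0 with the last 5 landmarks, 2 after thinning, 1 without clusters led by nuclear RNA and 55 within the 5000-barcode pair. Leaving out each mouse gave 0 (without the Hamp2 line) to 12 (without the Cyp1a2 line), with 1 without the Gls2/Oat line. Middle-low genes, 1, numbered 3 with no count filter, 0 at a mitochondrial share of at most 20%, 45 with no limit, 2 with 10% of cells removed as doublets, 1866 over all kept cells, 2 with narrower end zones, 3 with the first 5 landmarks, 0 after thinning, 9 within the 5000-barcode pair and 1 to 2 leaving out each mouse, 2 without the Cyp1a2, Gls2 or Hamp2 line. All but the DESeq2 count come from edgeR. Where the middle-high count was 0, the genes at an unadjusted p below 0.05 in both tests numbered 20 by DESeq2, 27 at a mitochondrial share of at most 20%, 29 with the UMI ratio score, 16 with the last 5 landmarks, 7 without the block and 35 without the Hamp2 line. For middle-low they numbered 26 at that mitochondrial share, 23 after thinning and 5 without the block. All kept cells include other cell types, and their effect on the middle counts was not tested. The smaller middle difference of Fam35a was -0.24 and that of Ikbkb -0.044 over all kept cells. Without clusters led by nuclear RNA it was -0.13 for Chd3 and -0.00097 for Ikbkb, and Chd3 was at -0.0025 in the 4000-barcode pair.

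The Hamp2 log2 fold change of -0.16 was 0.10 with total counts, which is about the shift of the median of all genes by 0.25, and -1.09 in the 4000-barcode pair (past the threshold), 0.71 in the 5000-barcode pair (past it the other way) and -0.50 to 0.16 leaving out each mouse, above 0 without the Cyp1a2 or the Gls2 line. C6 was at -0.18 over all kept cells and Klf6 at -0.13 in the 4000-barcode pair.

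With an estimated correlation 6 lists had a call, against 18. For 4 lists that were not called, the direction given by camera, which compares a list with all other genes, turned; the medians there were as follows. For cell cycle they were 0.18 with total counts, -0.17 with no mitochondrial limit, -0.18 with no doublets removed, -0.15 with boundaries from the pooled cells, -0.13 with the UMI ratio score, -0.055 with the first 5 and -0.15 with the last 5 landmarks, -0.079 in the 5000-barcode pair, -0.079 by fry and -0.13 to 0.069 leaving out each mouse. For immediate early genes they were 0.038 with the first 5 landmarks, 0.10 without clusters led by nuclear RNA and 0.095 in the 4000-barcode pair. For heat shock genes they were 0.24 with total counts, -0.010 without the block, 0.042 at a mitochondrial share of at most 20%, -0.026 with the UMI ratio score, 0.018 with the last 5 landmarks, -0.019 in the 5000-barcode pair and -0.044 to 0.00063 leaving out each mouse. For female-biased genes they were 0.26 without the block, 0.16 at a mitochondrial share of at most 20%, 0.19 without clusters led by nuclear RNA, -0.022 in the 4000-barcode pair and 0.14 to 0.48 leaving out each mouse.

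The hepatocyte-like share was 75.6% in the Gls2 and 75.7% in the Gls2/Oat line at a mitochondrial share of at most 20%. With no limit it was 84.0%, 82.3%, 81.1% and 74.0% in the 4 lines, and 80.96% in the Hamp2 line at resolution 2. The tdTomato log2 ratio from shares of cells with at least 2 UMIs was 3.14, -2.99, -0.014 and 1.57, and after thinning -0.13 in the Gls2/Oat and 0.94 in the Hamp2 line. The log2 ratio of carriers to others was -0.65 for Gls2, -1.59 for Oat and -2.004 for Hamp2 at a mitochondrial share of at most 20%, -0.47 for Cyp1a2 over all kept cells, -0.60 for Gls2 and -1.16 for Oat after thinning, and -0.46, -1.16 and -2.68 for Gls2, Oat and Hamp2 with TMM factors; all stayed below 0. tdTomato in the Hamp2 line rests on 1693 UMIs in all barcodes.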

Other observations

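Of the tests in this part, the comparison of library pairs with its batch test, the zone by pair interaction and the count of genes at any fold under random rankings were chosen after the results were seen, as were the genes named for them. Whole gene programmes differed between libraries, with 1 mouse per line. The immediate early and dissociation list, genes such as Fos and Jun that respond within minutes to stress, had medians of -0.39, -0.58, 0.31 and 0.47 on the log2 scale in the Cyp1a2, Gls2, Gls2/Oat and Hamp2 lines relative to the mean of the others, at percentiles 0, 0, 99.83 and 100 of 10000 random lists. In the same order, clusters led by nuclear RNA held 0.188%, 0.565%, 12.1% and 33.6% of hepatocyte-like cells. These clusters include cluster 16, which was led by acute phase genes. Their share is therefore no measure of RNA quality by itself, and RNA quality was not tested. The fatty acid oxidation and ketogenesis list lay at -0.52 (percentile 0) in the Gls2 line and 0.34 (percentile 99.94) in the Hamp2 line, opposite to the cholesterol synthesis list at 0.35 (percentile 100) and -0.55 (percentile 0). The male-biased list lay at 0.36 (percentile 100) in the Cyp1a2 line and -0.57 (percentile 0) in the Hamp2 line, although all 4 mice were female. Random lists do not copy genes that vary together, so the percentiles of these lists can overstate the differences. Among nuclear RNAs, Malat1 (log2 fold change -1.35), Neat1 (-1.27) and Xist (-0.82) were higher in the periportal zone, as was Alb (-0.86); these genes are outside the naming rule and were chosen after their values were seen.

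Hepatocytes of the 4000-barcode and 5000-barcode pairs were set apart by 35 of 2552 genes at least 2-fold, 12 higher in the first and 23 in the second pair, against 1 and 0 genes for the other ways to pair the libraries. The major urinary protein genes Mup17 (134 and 131 against 10.2 and 4.96 CPM) and Mup3 (4989 and 3683 against 935 and 719 CPM), the lipogenic regulator gene Srebf1 (137 and 141 against 41.6 and 41.5 CPM) and the landmark Cyp2f2 (531 and 620 against 72.9 and 98.3 CPM) were higher in the 4000-barcode pair. The acute phase genes Orm2 (28.0052 and 40.2 against 218 and 290 CPM) and Lcn2 (34.1 and 38.6 against 106 and 217 CPM), the stress cytokine gene Gdf15 (52.5 and 41.0 against 169 and 218 CPM) and the immediate early gene Fosb (12.6 and 10.5 against 57.0 and 40.8 CPM) were higher in the 5000-barcode pair. The zone difference itself differed between the pairs for 692 genes by the interaction test of edgeR (adjusted over all genes), 527 with the higher pericentral-to-periportal ratio in the 5000-barcode pair.

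For the genes that set the library pairs apart, depth was tested by thinning to 2000 UMIs, after which 52 genes were apart, 31 of the 35 among them. CPM are already scaled to depth, and thinning only evens the weight of the cells. This test therefore cannot decide about depth. Without the clusters led by nuclear RNA 32 genes were apart, 30 of the 35 among them, which argues against these clusters as the whole cause. A batch of library preparation or sequencing stays open: all 35 genes lie between pairs that also differ in barcodes kept and depth, and since no line is in both pairs, a batch and the lines cannot be told apart. The labels give no batch, and differences between mice in feeding, time of day or inflammation were not tested.

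Splits of the samples decide nothing about chance here. The real split of the 8 outer sums gave 3231 genes, the highest of the other 34 gave 1, and 1 of 35 splits, the real one, gave as many. Among the 8 splits that part each mouse's pair of sums, the highest other gave 0. The zones were ranked on expression, so the other splits mix the ranked axis into the spread. For the middle-high and middle-low genes, 2 of 80 relabellings of the zones within mice gave as many as the real 7, the real one included. Each relabelling that mixed zones over mice gave 0 for the same reason, and the highest other, 155, placed the middle label on the periportal zone in all 4 mice, which points to a structure of the samples. Ranking cells by any expression score was tested with 20 draws of random genes in place of the landmarks. The highest count at least 2-fold was 299 against 400 with the landmarks (median of draws 18). No draw reached the full count of 2-fold genes, but such a ranking could account for a part of them. In 4 of 20 draws as many genes were called at any fold, up to 4104 against 3231 (median 638), so ranking cells by any expression score could account for the count of genes at any fold, and this count is no measure of zonation by itself. The gene lists were not run under these draws.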
